A study of Mus musculus with 10 samples.

How the data were processed

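Polyadenylated RNA of αTC1 cells was sequenced after 48 h in 10 μM enzalutamide (5 libraries) or DMSO (5 libraries), and each library was placed in its group by its title and treatment label. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the mm10 genome build, without versions or roles. The authors deposited a table of whole-number counts per Ensembl gene, with 33212 genes and 1 column per library, and the labels do not say whether these counts came directly from reads or from StringTie's transcript estimates. The strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of overlapping or antisense genes are less certain than others. The same holds for families with near-identical copies, such as the H2 antigen genes, mitochondrial genes with nuclear copies, and ribosomal protein and glycolytic enzyme genes with processed pseudogenes. A second deposited table held a signal scaled by library, from the authors' normalization. It had 20240 genes, those with a total count of at least 2, and in all 20039 that could be matched by a unique symbol each value times DESeq2's median-of-ratios size factor gave the count within 0.01. In it 25 symbols had been turned into dates, so gene names were taken from the count table. All columns of both tables were matched to samples by name, and 0 columns of per-library values were left unused.

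The count table was the basis of the main test and the scaled signal of an alternative. Totals were between 59557697 and 68603842 counts per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed by edgeR's filterByExpr with the groups given, which left 14156 genes, and libraries were scaled by the trimmed mean of M values. Enzalutamide was compared with DMSO by edgeR's quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 fold change is enzalutamide against DMSO. Every SE is the absolute log2 fold change divided by the square root of the test's F statistic, and 95% intervals apply a normal quantile to it. CPM values use the scaled library sizes, and every ± is the SD over 5 libraries. The biological coefficient of variation was 8.39%. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom between 8.98 and 35.3), so all 10 were counted as separate samples. The labels call them biological replicates but do not say whether they were separate cultures grown on separate days, so the p-values measure the spread between these libraries.

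Gene lists, fixed genes, tests and the rule for named genes were set before the data were examined. The rule named 14 fixed genes and, in each list, up to 4 passing members with the lowest adjusted p. It also named the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, at least 5 CPM in 1 group, an established symbol and no overlap between the groups' CPM values. Members that went against the rest of their list were named after their values were seen, namely Slc7a2, Eno2, Uqcrq, Ndufb9, Ndufs7, mt-Nd1, mt-Nd2, Tm7sf2, Sel1l, E2f1, Atp6v1h, Per1 and Pde4d, as were Gdf15, Pcsk2, Irx1, Irx2, Ero1lb, Abat and Nr1i3. So were Jun, Junb, Ier2 and Dusp1, which did not pass. Results for some of the genes that these rules cover are not reported here. Where a symbol occurred more than once, as for Pde4d, the entry with the highest mean count was used in a list. The 30 lists were tested with camera at a preset correlation of 0.01 between members, two-sided, with adjustment over the lists, and again with an estimated correlation and with fry, which tests a list's genes without comparing them with other genes. Gene positions and biotypes came from GENCODE M21 on GRCm38/mm10, where 31975 identifiers of the count table (96.3%) were found.

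Alternatives set in advance were relative log expression size factors, total-count scaling, no filter on low counts, a mean CPM of at least 1, the replicate number as a block, summing entries that share a symbol, leaving out each library in turn, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the authors' scaled signal plus a pseudocount of 1 or 8, and a minimum change of 2-fold. Removal of per-library trends with transcript GC content and length, and omission of the 13 mitochondrially encoded mRNAs and Gcg, were added after the data were seen. The pipeline was tested on simulated data, drawn for 14156 genes from the library sizes of the comparison of enzalutamide with DMSO and the means of the DMSO libraries. It recovered 44% of genes changed 1.2-fold, 64% of those changed 1.5-fold, 85.4% at 2-fold and 89.8% at 3-fold, and 7 of the 146 genes called were unchanged. Only 48 to 50 genes were changed at each fold, whereas 37.9% of genes were called in the real data. These shares therefore do not give the recovery of the real test. Camera recovered the 1 simulated list changed 1.3-fold and called 0 of the others. The simulated genes varied independently, so this does not show how camera performs on members that vary together. In the real data the estimated correlation reached 0.798, for ribosomal protein genes.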

Results

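RNA sequencing of polyadenylated transcripts was carried out on αTC1 cells, a mouse line derived from a pancreatic tumour of glucagon-secreting α cells. The cells were exposed for 48 h to 10 μM enzalutamide, an antiandrogen used in prostate cancer, or to the solvent DMSO. Each group held 5 libraries that the labels call biological replicates, and the series title places the experiment in work on metabolism and the formation of insulin-producing β cells from α cells. The deposited counts summed to between 59557697 and 68603842 per library. Group totals did not differ beyond the spread between libraries (n = 5 each; exact two-sided permutation test, p = 0.27). At this depth 3 counts, the limit that a count of 0 allows, corresponded to between 0.0437 and 0.0504 CPM (counts scaled to a common library total), a limit that covers counting error only. The first principal component of log2 CPM carried 27.3% of the variance and separated the groups, with DMSO libraries between -24.61 and -21.35 and enzalutamide libraries between 20.94 and 26.31.

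**Figure D1:**
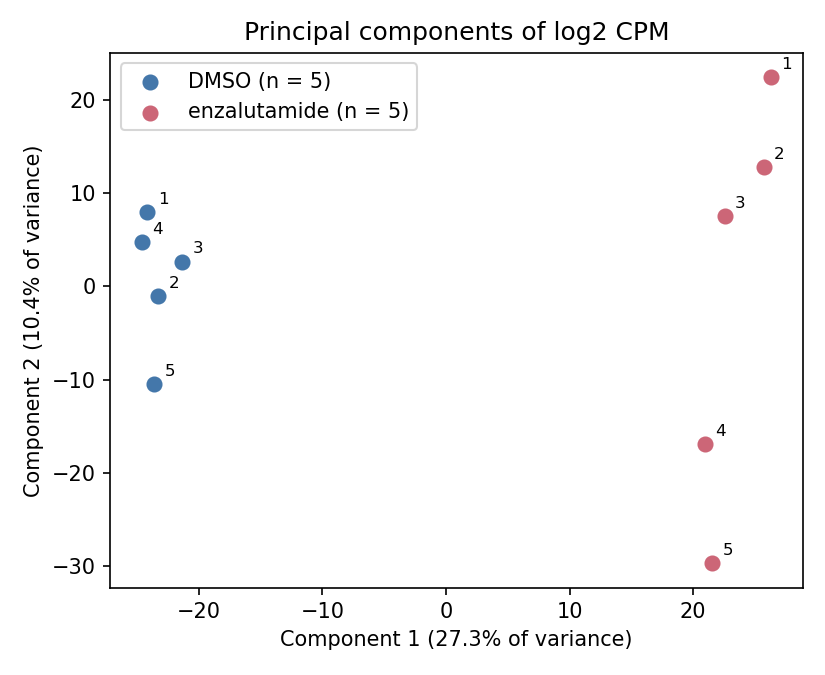
Position of each of the 10 libraries on the first principal component (horizontal, 27.3% of variance) and the second (vertical, 10.4% of variance) of log2 CPM, with blue points for DMSO, red points for enzalutamide and the replicate number beside each point. The groups lie apart on the first component, and the enzalutamide libraries spread further than the DMSO libraries on the second.

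Enzalutamide-treated αTC1 cells had lower expression of Gcg, the glucagon gene, and of other α cell genes, and higher expression of genes induced through the stress transcription factor ATF4. Gcg fell from 15269 ± 440 to 8466 ± 389 CPM (SD, n = 5 each), and 26 of 27 measured ATF4 list genes rose, led by Trib3, a pseudokinase, which rose 8.41-fold. Of 14 measured cAMP-induced and immediate early genes 8 fell and 2 rose. Nr4a1, which encodes an orphan nuclear receptor, was 11.3-fold lower, and 26 of 26 genes of the G2 and M phases of the cell cycle fell. Genes of β cells did not rise: 0 of 10 measured members of that list were higher and 5 were lower.

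The comparison of enzalutamide with DMSO covered 14156 genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2696 genes were higher and 2662 lower in enzalutamide at an adjusted p under 0.05, which is 37.9% of those tested. Of the changed genes 50.3% were higher. Most changes were small. The median absolute log2 fold change of the 5358 changed genes was 0.25, and 146 genes rose and 101 fell by more than 2-fold. The 5 values of each group did not overlap for 3799 genes, 26.8% of those tested, where chance gives 0.794%. With libraries scaled to total counts alone the split was 3285 higher and 2131 lower, so that 60.7% of calls were higher.

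Among 14 genes fixed in advance, most of them for islet hormones and islet identity, 7 had enough counts to test, and 3 of these fell and 0 rose (3 adjusted over the list alone). Fkbp5, which encodes a co-chaperone and is commonly induced by androgens, was at 71.9 ± 4.89 CPM in DMSO and 75.2 ± 3.23 CPM in enzalutamide (log2 fold change 0.06, SE 0.0473, adjusted p = 0.324). Gcg (ENSMUSG00000000394; chromosome 2, 62474530 to 62483650 of GRCm38/mm10) had a log2 fold change of -0.85 (SE 0.0289, adjusted p = 5.74e-13). Its share of all counts was 1.51 ± 0.0431% in DMSO and 0.857 ± 0.0363% in enzalutamide.

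Among the fixed genes, those for hormones and lineages of other islet cells ranged from 0 counts in every library to 46.2 CPM. None of these that could be tested passed. Ins1, Pdx1, Sst and Ppy, which encode an insulin, a β cell transcription factor, somatostatin and pancreatic polypeptide, had 0 counts in every library. Ins2, the other mouse insulin gene, was at 0.626 ± 0.138 CPM in DMSO and 0.409 ± 0.12 CPM in enzalutamide, a difference that did not pass (log2 fold change -0.62, SE 0.332, adjusted p = 0.164). Neurog3, the endocrine progenitor factor, had 11 counts in DMSO library 1 and 0 elsewhere, and Pax4, a factor of β cell development, had 10 counts in enzalutamide library 2 and 0 elsewhere. Mafa, a factor of mature β cells, was at 1.03 ± 0.759 and 0.989 ± 0.439 CPM (adjusted p = 0.938). Nkx6-1, another β cell factor, was at 45.2 ± 2.28 and 46.2 ± 1.68 CPM in DMSO and enzalutamide (log2 fold change 0.03, SE 0.0451, adjusted p = 0.653).

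The 8 largest rises that met the rule for named genes were those of Trib3, L1cam, Slc6a9, Slc7a3, Chac1, Cth, Atf5 and Angptl6, and for each of them all 5 enzalutamide values lay above all 5 DMSO values. Trib3 (chromosome 2, 152337422 to 152344032) rose from 8.1 ± 1.87 to 68 ± 5.38 CPM (log2 fold change 3.07, SE 0.113, adjusted p = 1.44e-12). L1cam, a neural cell adhesion molecule, rose 5.38-fold from 1.14 ± 0.276 CPM. The amino acid transporters Slc6a9, which carries glycine, and Slc7a3, which carries cationic amino acids, rose by log2 fold changes of 2.32 and 2.28. Chac1, a glutathione-degrading enzyme on chromosome 2 (119351229 to 119354381), rose from 13 ± 0.762 to 59.5 ± 2.65 CPM (log2 fold change 2.19, SE 0.0523, adjusted p = 6.09e-15). Cth, which makes cysteine from cystathionine, rose by 2.04 on the log2 scale, and Angptl6, a secreted angiopoietin-like protein, by 1.77. Atf5, a stress-induced transcription factor (chromosome 7, 44812256 to 44816658), rose from 98 ± 5.4 to 384 ± 14.1 CPM (log2 fold change 1.97, SE 0.0401, adjusted p = 8.43e-16).

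The 8 largest falls were those of Nr4a1, Fos, Dusp6, Prlr, Ryr2, Nr4a2, Etv5 and Agt, again with no overlap between the groups' values. Nr4a1 (chromosome 15, 101254269 to 101274795) fell from 67.5 ± 2.76 to 5.95 ± 0.306 CPM (log2 fold change -3.50, SE 0.053, adjusted p = 1.14e-17). Fos, a subunit of the AP-1 transcription factor, fell from 5.37 ± 0.728 to 0.988 ± 0.215 CPM. Dusp6, a phosphatase of ERK (chromosome 10, 99263231 to 99267489), fell from 16.8 ± 1.26 to 3.24 ± 0.698 CPM (log2 fold change -2.37, SE 0.121, adjusted p = 1.17e-10), and the ETS factor gene Etv5 fell with a log2 fold change of -1.98. Prlr, the prolactin receptor (chromosome 15, 10177238 to 10349180), fell from 117 ± 3.6 to 25.9 ± 2.34 CPM (log2 fold change -2.17, SE 0.0534, adjusted p = 8.08e-15). The log2 fold changes were -2.10 for Ryr2, a calcium release channel, -2.06 for the nuclear receptor gene Nr4a2, and -1.78 for Agt, the angiotensin precursor.

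**Figure D2:**
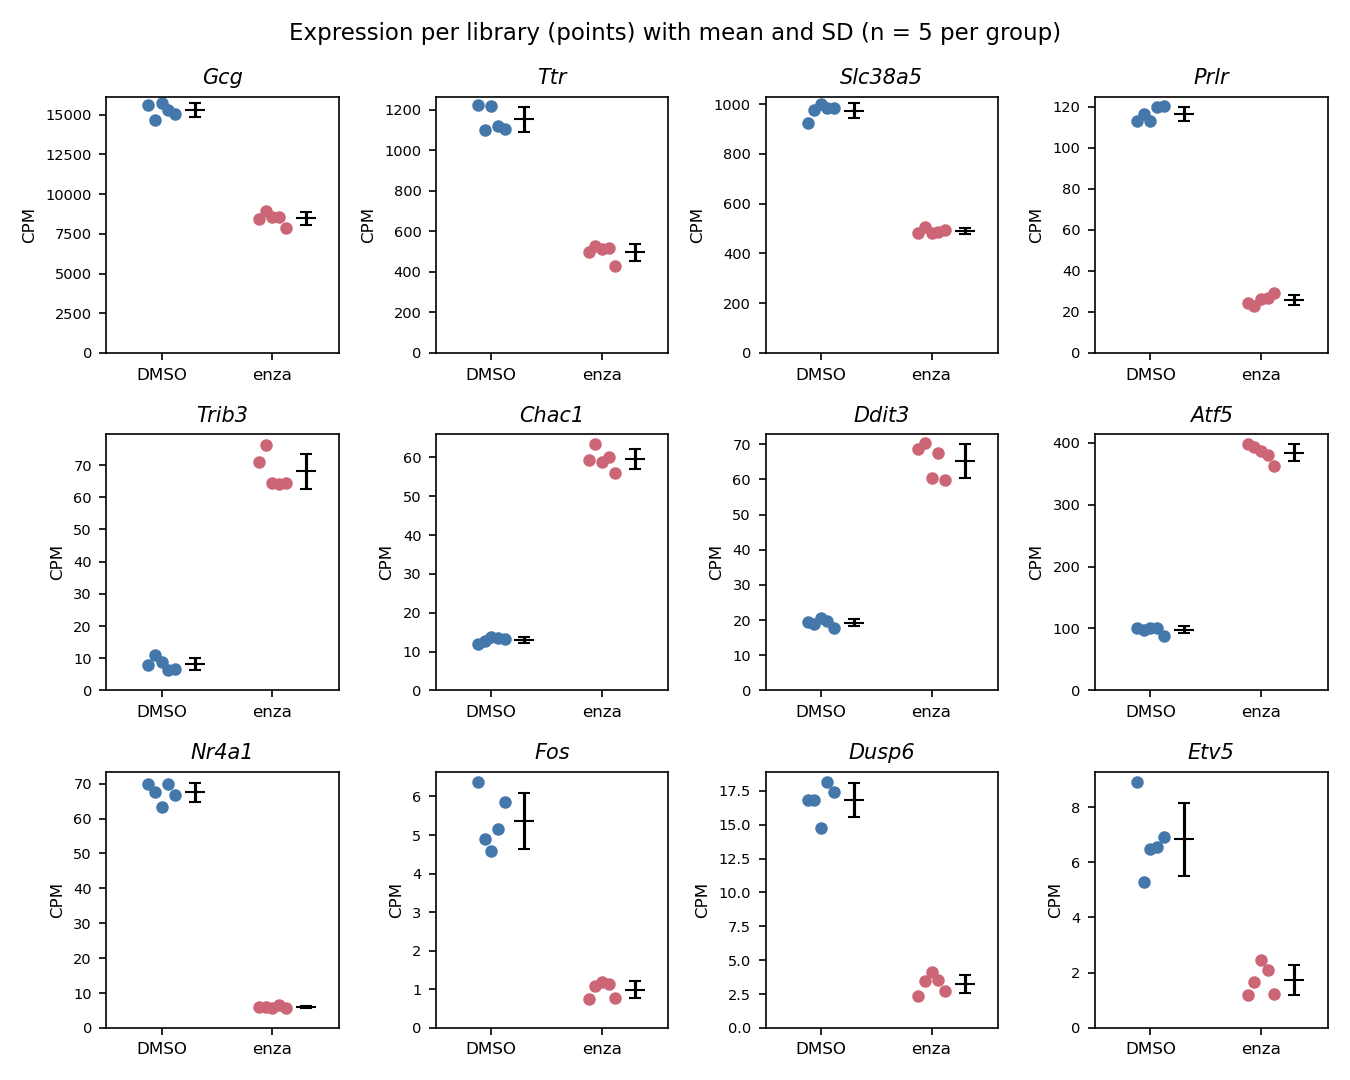
Expression in CPM (vertical axes, from 0) of 12 genes in DMSO (blue) and enzalutamide (red), with 1 point per library and a bar for the mean and SD of 5 libraries. Gcg, Ttr, Slc38a5 and Prlr were lower in enzalutamide, Trib3, Chac1, Ddit3 and Atf5 higher, and Nr4a1, Fos, Dusp6 and Etv5 lower, with no overlap between groups in any of the 12 panels.

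For 30 gene lists fixed in advance, camera with a preset correlation of 0.01 between members called 13, 3 higher and 10 lower. With a correlation estimated from the data it called 6 of these, namely the ATF4, α cell, β cell, S phase, G2 and M phase, and cAMP and immediate early lists, which are described first. Of 100 splits of the 10 libraries into 5 and 5, 10 gave at least 13 lists under the preset correlation, the real split among them. The other 9 all kept 4 libraries of each group together, and the 82 splits into 3 and 2 libraries of each group gave at most 12. With an estimated correlation no other split gave any list.

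The list of amino acid stress and ATF4 genes had 26 of 27 measured members higher and 0 lower (26 and 0 adjusted over the list alone), with a median log2 fold change of 0.95. For the ATF4 list the camera adjusted p was 4.83e-124 (adjusted p = 6.17e-05 with an estimated correlation). Besides Chac1, its examples were Aldh1l2, a mitochondrial folate enzyme (log2 fold change 1.17, SE 0.0299), Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (1.37, SE 0.0367), and Ddit3, which encodes CHOP (1.76, SE 0.0566). Gdf15, a stress-induced cytokine and the member that did not pass, was at 0.0618 CPM in DMSO and 0.185 CPM in enzalutamide (adjusted p = 0.131, and 0.0128 without DMSO library 1 and 0.0273 in limma-voom).

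The α cell list had 7 of 13 measured members lower and 1 higher (7 and 1 adjusted over the list alone), with a median log2 fold change of -0.24. For the α cell list the camera adjusted p was 9.6e-10 (adjusted p = 0.0035 with an estimated correlation). Slc38a5, a glutamine transporter, fell from 974 ± 30.5 to 490 ± 10.6 CPM, and Ttr, the thyroxine carrier transthyretin, from 1153 ± 62.3 to 496 ± 40.7 CPM. The member that rose was Slc7a2, an arginine transporter (log2 fold change 0.26, SE 0.0441, adjusted p = 0.000141). Members that did not pass included Pcsk2, the protease that processes proglucagon, with a log2 fold change of 0.03 (adjusted p = 0.313, and 0.0185 with total-count scaling), and the Iroquois factor genes Irx1 (0.02, adjusted p = 0.727, but -0.10 and adjusted p = 0.0236 with GC and length trends removed) and Irx2 (0.01, adjusted p = 0.857, and -0.04 with these trends removed). These members and Slc7a2 were chosen after their values were seen.

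The β cell list had 5 of 10 measured members lower and 0 higher (5 and 0 adjusted over the list alone), with a median log2 fold change of -0.24. For the β cell list the camera adjusted p was 4.41e-06 (adjusted p = 0.00575 with an estimated correlation). The genes that fell were Prlr, G6pc2, an islet glucose-6-phosphatase (-0.58, SE 0.0752), Slc30a8, the zinc transporter of secretory granules (-0.24, SE 0.035), Hadh, a fatty acid oxidation enzyme high in β cells (-0.24, SE 0.0411), and Ero1lb, an oxidase of protein folding (-0.21, SE 0.0599). In αTC1 cells these transcripts were present without detectable Ins1 or Pdx1.

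Proliferation genes were lower. In the S phase list 21 of 26 members fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -0.22. For the S phase list the camera adjusted p was 3.84e-11 (adjusted p = 0.0035 with an estimated correlation). The ribonucleotide reductase subunit genes Rrm2 and Rrm1 fell with log2 fold changes of -0.66 and -0.39, and Tyms, the thymidylate synthase, with -0.42. The riser was the cell cycle transcription factor gene E2f1 (0.16, adjusted p = 0.02). The adjusted p of E2f1 was up to 0.0599 without DMSO library 2, DMSO library 5 or enzalutamide library 2, and 0.0813 with GC and length trends removed (log2 fold change 0.09). It was 0.0534 without a filter on low counts and up to 0.0537 in limma-trend. The G2 and M phase list had 26 of 26 members lower (26 adjusted over the list alone), with a median of -0.37. For the G2 and M phase list the camera adjusted p was 2.21e-26 (adjusted p = 0.000366 with an estimated correlation). Among its members were the mitotic cyclin Ccnb1 (-0.51), the kinase Plk1 (-0.50) and the topoisomerase Top2a (-0.38).

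The cAMP and immediate early list had 8 of 14 members lower and 2 higher (8 and 2 adjusted over the list alone), with a median of -0.40. For the cAMP and immediate early list the camera adjusted p was 9.28e-14 (adjusted p = 0.00645 with an estimated correlation). Nr4a1, Nr4a2 and Fos led it, followed by Sik1, a cAMP-induced kinase (-0.38, SE 0.0301). The clock gene Per1 (0.50) and the cAMP phosphodiesterase gene Pde4d (0.19) were the members that rose.

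**Figure D3:**
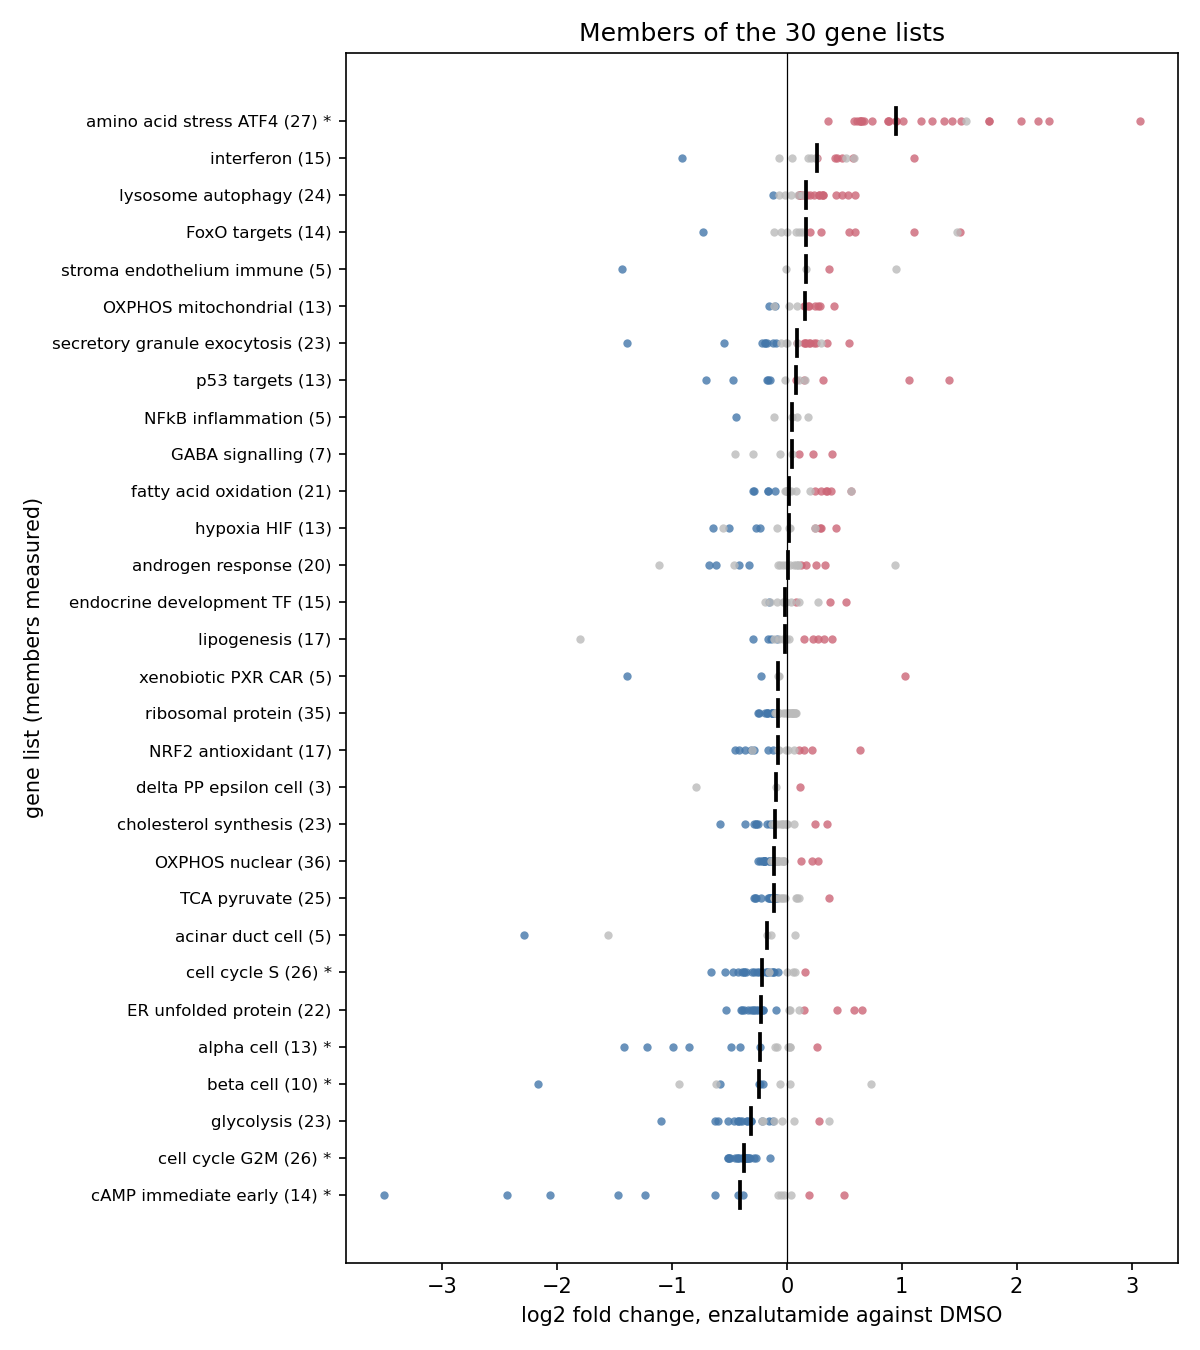
Log2 fold change of enzalutamide against DMSO (horizontal axis) for every measured member of the 30 gene lists, with the number measured in parentheses, red points for members that passed the test as higher, blue for lower and grey for neither, and a vertical bar for each list's median. Asterisks mark the 6 lists called with an estimated correlation, from the ATF4 list with a median of 0.95 at the top to the cAMP and immediate early list with -0.40 at the bottom.

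Lists of energy metabolism were called by camera with the preset correlation only. In fry the glycolysis (adjusted p = 0.000987) and TCA cycle (0.0063) lists passed, as did the mRNAs encoded in mitochondrial DNA (0.00987). Glycolysis had 16 of 23 members lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -0.31. For glycolysis the camera adjusted p was 1.46e-06 (adjusted p = 0.319 with an estimated correlation). The glycolytic enzyme genes Pgk1 (-0.51), Pgam1 (-0.42), Tpi1 (-0.42) and Pkm (-0.39) fell, and Eno2, the neuronal enolase, rose (0.28). In the TCA cycle and pyruvate list 14 of 25 members fell and 1 rose (16 and 3 adjusted over the list alone), with a median of -0.11. For the TCA cycle list the camera adjusted p was 0.0197 (adjusted p = 0.631 with an estimated correlation, 0.0532 with total-count scaling, and 0.058 with GC and length trends removed). Ogdh and Mdh2, both enzymes of the cycle, each had a log2 fold change of -0.27, and Suclg2, a succinyl-CoA ligase subunit, rose (0.37). Nuclear genes of oxidative phosphorylation had 17 of 36 members lower and 3 higher (18 and 3 adjusted over the list alone), with a median of -0.11. For nuclear oxidative phosphorylation the camera adjusted p was 0.00979 (adjusted p = 0.728 with an estimated correlation, and 0.0713 in fry). Of these, the ATP synthase subunit genes Atp5b and Atp5a1 had -0.21 and -0.20 and Uqcrc2 of complex III had -0.19. The risers were Uqcrq (0.27), Ndufb9 (0.22) and Ndufs7 (0.13, adjusted p = 0.0361). Ndufs7 had an adjusted p of 0.0531 to 0.0975 without any 1 of DMSO libraries 1, 2 and 4 and enzalutamide libraries 1, 2, 3 and 4, of 0.0705 without a filter and of up to 0.0836 in limma-trend. Without enzalutamide library 5 the adjusted p was 0.0529 for the TCA cycle list and 0.0684 for nuclear oxidative phosphorylation.

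The mRNAs encoded in mitochondrial DNA moved the other way, with 8 of 13 higher and 2 lower (9 and 3 adjusted over the list alone), a median of 0.15 and a camera adjusted p = 0.0256 (adjusted p = 0.631 with an estimated correlation). The respiratory chain subunit genes mt-Co1, mt-Co2 and mt-Cytb had log2 fold changes of 0.41, 0.27 and 0.25, and the complex I subunit genes mt-Nd1 and mt-Nd2 had -0.16 and -0.10. For mt-Nd2 the adjusted p of 0.0121 became 0.131 with GC and length trends removed (log2 fold change -0.06), 0.0628 with total-count scaling and 0.0536 and 0.0915 in limma-trend. With these trends removed mt-Nd1 had -0.10 (adjusted p = 0.0201). Mitochondrial genes took 6.33 ± 0.188% of counts in DMSO and 7.41 ± 0.268% in enzalutamide (exact two-sided permutation test, p = 0.00794, the smallest that 5 against 5 libraries can give).

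The remaining called lists also lost the call with an estimated correlation. In the lysosome and autophagy list 18 of 24 measured members rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.17. For lysosomes and autophagy the camera adjusted p was 4.5e-08 (adjusted p = 0.147 with an estimated correlation). Its leading members were Grn, the progranulin gene (0.54), Hexa, a hexosaminidase subunit (0.59), the calcium channel gene Mcoln1 (0.42) and Lamp2 (0.28). The member that fell was Atp6v1h, a proton pump subunit (-0.12, adjusted p = 0.0252). Its adjusted p was up to 0.0767 without DMSO library 3 or 4 or enzalutamide library 1 or 5, 0.0958 with total-count scaling, 0.056 without a filter and up to 0.0543 in limma-trend. The unfolded protein list of the endoplasmic reticulum had 15 of 22 members lower and 4 higher (15 and 4 adjusted over the list alone), with a median of -0.22. For the unfolded protein list the camera adjusted p was 0.00979 (adjusted p = 0.125 with an estimated correlation). The chaperone gene Hsp90b1 fell (-0.39), whereas Herpud1 (0.59) and Sel1l (0.15), both of protein degradation, and the stress sensor genes Ern1 (0.65) and Atf6 (0.43) rose. Cholesterol synthesis had 10 of 23 measured members lower and 2 higher (10 and 2 adjusted over the list alone), with a median of -0.10. For cholesterol synthesis the camera adjusted p was 0.0204 (adjusted p = 0.183 with an estimated correlation). The synthesis genes Ebp (-0.59), Idi1 (-0.29) and Cyp51 (-0.25) and the sterol carrier gene Stard4 (-0.36) fell, and Tm7sf2 (0.35) was among those that rose.

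Lists for androgen response, secretion and other cell types were not called by camera. In fry the endocrine development (adjusted p = 0.0259), acinar and duct (0.000561) and GABA (0.00506) lists passed. Of 20 measured androgen response genes 4 were higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.717), with Iqgap2 (-0.67) and Arid5b (-0.62) lower and Herc3 (0.26) and Sgk1 (0.17) higher. In the secretory granule list 10 of 23 members rose and 8 fell (10 and 8 adjusted over the list alone; adjusted p = 0.751). There Vgf, a granin-like precursor, and Pam, a peptide-amidating enzyme, fell with -1.39 and -0.54, and the channel genes Abcc8 (0.35) and Cacna1d (0.54) rose. Endocrine development factors had 3 of 15 measured members higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.613), with Fev (0.51), Myt1 (0.38) and Isl1 (0.08) higher and St18 (-0.15) lower. Isl1 had an adjusted p of 0.026, and of up to 0.0685 without any 1 of DMSO libraries 2, 3 and 4 and enzalutamide library 3. Of the δ, PP and ε cell list 3 genes were measured, with 1 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.998), namely Rbp4 (0.12). Rbp4 had an adjusted p of 0.0223, and of 0.0651 and 0.0503 without DMSO library 5 and enzalutamide library 4, 0.0614 without a filter and up to 0.0949 in limma-trend. The acinar and duct list had 1 of 5 measured members lower, Spp1 (-2.29), and 0 higher (1 and 0 adjusted over the list alone; adjusted p = 0.214). The list for stroma, endothelium and immune cells had 1 of 5 higher, Pdgfra (0.37), and 1 lower, Col1a2 (-1.44; 1 and 1 adjusted over the list alone; adjusted p = 0.885). GABA signalling had 3 of 7 measured members higher and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.451), namely Aldh5a1 (0.39), Gabbr1 (0.23) and Abat (0.11, adjusted p = 0.0386). Abat had an adjusted p of 0.0566 to 0.113 without any 1 of DMSO libraries 1, 3 and 4 and enzalutamide libraries 3, 4 and 5.

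Other stress and metabolic lists were not called by camera either. The interferon, FoxO and ribosomal protein lists passed with camera under some alternatives. In fry, which does not compare a list with other genes, the interferon (adjusted p = 1.38e-06), FoxO (3.41e-05), p53 (0.00277), NRF2 (0.00431), fatty acid oxidation (0.0217) and xenobiotic (0.0259) lists passed. Interferon genes had 6 of 15 measured members higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0547), with the class I antigen genes H2-D1 (0.44) and H2-K1 (0.57) higher and the RNA sensor gene Ifih1 (-0.91) lower. The interferon list had an adjusted p of 0.0158 without a filter on low counts. It had 0.0477 to 0.0493 with a mean CPM of at least 1 or without any 1 of DMSO libraries 1 and 3 and enzalutamide library 4. FoxO targets had 6 of 14 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0607), with Klf15 (1.51) and Fbxo32 (1.10) higher and Txnip (-0.73), a glucose-responsive gene, lower. The FoxO list had an adjusted p of 0.00969 without a filter, and of 0.0469 to 0.0493 without any 1 of DMSO library 1 and enzalutamide libraries 1, 2 and 4. For p53 targets the split was 5 higher and 5 lower of 13 (6 and 5 adjusted over the list alone; adjusted p = 0.451), with Trp53inp1 (1.41) and Bbc3 (1.06) higher and Plk2 (-0.70) lower. NRF2 antioxidant genes had 4 of 17 higher and 7 lower (4 and 8 adjusted over the list alone; adjusted p = 0.214), with the haem oxygenase gene Hmox1 (0.64) higher and the pentose phosphate genes Taldo1 (-0.41) and Pgd (-0.36) lower. Hypoxia genes had 4 of 13 higher and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.998), with Vegfa (0.43) higher and Higd1a (-0.50) lower. Fatty acid oxidation had 6 of 21 higher and 5 lower (6 and 5 adjusted over the list alone; adjusted p = 0.275), with Cpt1a (0.56), the carnitine acyltransferase of fatty acid entry, higher and Hadha (-0.29) and Hadhb (-0.28) lower. Lipogenesis had 5 of 17 higher and 4 lower (5 and 5 adjusted over the list alone; adjusted p = 0.998), with the desaturase genes Scd2 (-0.30) lower and Fads1 (0.22) higher. The xenobiotic list had 1 of 5 higher, Gstm1 (1.03), and 2 lower, Alas1 (-0.23) and Nr1i3 (-1.39), with 1 and 2 adjusted over the list alone (adjusted p = 0.585). Nr1i3 itself had an adjusted p of 0.0443, and of 0.0667 to 0.145 without any 1 of DMSO libraries 3 and 5 and enzalutamide libraries 1, 2, 4 and 5, 0.114 without a filter and up to 0.0907 in limma-trend. NF-κB genes had 1 of 5 lower, Nfkb2 (-0.44), and 0 higher (1 and 0 adjusted over the list alone; adjusted p = 0.864). Ribosomal protein genes had 12 of 35 lower and 0 higher (12 and 0 adjusted over the list alone; adjusted p = 0.111), for example Rpl6 (-0.25) and Rpl27 (-0.24). The ribosomal protein list had an adjusted p of 0.0194 without enzalutamide library 2 and of 0.0187 without a filter. The median, the mean and the camera test did not all have the same sign for the endocrine development, secretory granule, androgen response, xenobiotic, GABA, lipogenesis, hypoxia and NF-κB lists.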

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

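Tests chosen only after the result was seen were the splits of the libraries for gene counts and for lists with an estimated correlation, the effect of abundant transcripts, a lower share of α cells, a shift towards β cell transcription, stress of the endoplasmic reticulum, and shifts shared between libraries, together with the removal of GC and length trends as an alternative and the spread applied to the mitochondrial chaperone count.

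A library far from the other 4 of its group was found for 21 of 290 groups of values, where chance gives about 1 in 20. Enzalutamide library 2 stood apart most often. Its mitochondrial share of counts was 7.88%, against 7.21 to 7.36% in the others, and its CPM values were 6600 for mt-Co2, 9577 for mt-Cytb, 6431 for mt-Nd1, 4986 for mt-Nd2, 919.8 for Tpi1, 196.6 for Cpt1a, 199.1 for Irx2, 98.6 for E2f1 and 626.9 for Aars. Without this library 5354 genes changed. Pax4 was at 0.149 CPM in enzalutamide library 2 and Neurog3 at 0.172 CPM in DMSO library 1, with 0 in the other libraries of each group. Among genes that rose, Cth was at 5.24 CPM in DMSO library 4 (6.85 to 7.31 in the others), Atf5 at 88.6 in DMSO library 5 (98 to 101.6), Aldh1l2 at 175.8 in DMSO library 3 (181.7 to 184), Herpud1 at 82.9 in enzalutamide library 5 (86.3 to 87.2) and Pde4d at 70.9 in DMSO library 3 (64.6 to 66.4). Gdf15 was at 0.219 CPM in DMSO library 1 and at no more than 0.0456 in the other DMSO libraries. Among genes that fell, Nr4a1 was at 6.48 CPM in enzalutamide library 4 (5.71 to 5.88), Nr4a2 at 4.27 in enzalutamide library 1 (5.22 to 5.43) and Ccnb1 at 149.9 in enzalutamide library 3 (136.3 to 139.5).

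Chance is unlikely to account for the number of changed genes. Of 100 splits drawn from the 126 possible, the real split gave 5358 genes and the highest other 2. Thus 1 of 100 was as large. For the number of lists under camera's preset correlation it cannot be excluded by the count of splits, as 10 of the 100 gave at least the real 13 and the highest other gave 16. All 9 others that did so kept 4 libraries of each group together and so still held much of the treatment contrast. The 82 splits into 3 and 2 gave at most 12. With an estimated correlation the real split gave 6 lists and the highest other 0, so that 1 of 100 was as large. Every other split placed treated and control libraries in the same group, which adds the treatment difference to the spread within groups. The low counts of the other splits therefore do not show how many calls chance gives between groups treated alike.

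The first pattern weighed was the lower Gcg and α cell list. Abundant transcripts could shift the scale of all other genes, but the median of all genes moved only to a log2 fold change of 0.0412 under total-count scaling, and removal of GC and length trends left Gcg at -0.78. A lower share of α cells in the treated wells, among cells without these markers, would lower the markers alike. Instead, 7 of 13 measured members had a 95% interval above a level midway between 0 and the Gcg change. A lower share of Gcg-rich cells among cells that keep the other markers would not be seen by this comparison and was not tested. A general shift from α towards β cell transcription would raise more β cell genes than it lowers, whereas 0 were higher and 5 lower. Lower transcription of some α cell genes after enzalutamide remains as a hypothesis, found and tested on the same data. The fall was not confined to the α cell list, as the α and β cell lists both had a median log2 fold change of -0.24. Only 10 of the 20 β cell list genes were measured, so equal medians do not show that α and β cell genes fell alike.

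The second was the higher ATF4 list, of which 26 of 26 risers still rose with GC and length trends removed. Stress of the endoplasmic reticulum that raises its chaperones was looked for in the unfolded protein list, where 15 of 22 members fell and 4 rose. The fallers included the chaperone gene Hsp90b1 (-0.39), and the risers the stress sensor genes Ern1 (0.65) and Atf6 (0.43). Camera did not call the list with an estimated correlation (adjusted p = 0.125). Stress that acts through ATF4 without raising chaperones would not be seen by this comparison, so stress of the endoplasmic reticulum stays open. A wider ATF4-type response that includes aminoacyl-tRNA synthetases is consistent with 13 of 20 synthetase genes being higher and 3 lower. Mitochondrial protein-folding stress cannot be told apart from its absence. In a 10-gene chaperone and protease list 3 members were higher and 4 lower, a difference within counting spread. The rule set in advance read fewer rises than falls as evidence against such stress, and was changed after the result was seen. Camera called that list higher with the preset correlation (adjusted p = 0.0272) but not with an estimated one (adjusted p = 0.176). What starts the response was not tested.

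The third was the lower glycolysis, TCA and nuclear OXPHOS lists. Trends with GC content and length are argued against as the whole cause, since 47 of 47 members that fell still fell with the trends removed, although the TCA cycle list then had an adjusted p of 0.058. Shifts that the members share between libraries of 1 group may account for the camera calls, as its lowest adjusted p with an estimated correlation was 0.319. Fry, which allows for correlated members but does not compare a list with other genes, passed glycolysis (adjusted p = 0.000987) and the TCA cycle (0.0063). It did not pass nuclear oxidative phosphorylation (0.0713). The 2 tests differ for glycolysis and the TCA cycle, so this explanation stays open. The falls of single members stand on their own gene tests, and whether they reflect altered metabolism after enzalutamide was not tested.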

How the results depend on the processing

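Of the alternatives in this part, removal of GC and length trends and omission of mitochondrial mRNAs with Gcg were chosen only after the results were seen. The number of changed genes stayed between 4884 (no filter) and 5782 (GC and length trends removed) over all alternatives without a size threshold, and between 4888 and 5354 when any 1 library was left out. A 2-fold minimum left 247 genes, 146 higher and 101 lower, by construction. DESeq2 called 5512 and limma-voom 5366. The only alternative that turned the sign of called genes was the removal of GC and length trends, with 16 of 5328. The lists called were 6 with an estimated correlation, 21 with fry, which asks another question, and 11 to 15 with any 1 library left out. Leaving out enzalutamide library 5 ended the calls of the TCA cycle (0.0529) and nuclear oxidative phosphorylation (0.0684) lists. Without a filter the interferon, FoxO and ribosomal protein lists passed, with adjusted p-values of 0.0158, 0.00969 and 0.0187. They also passed with 1 library left out, ribosomal proteins without enzalutamide 2 (0.0194), interferon without DMSO 1 or 3 or enzalutamide 4 (0.0477 to 0.0493; 0.0493 with a mean CPM of at least 1) and FoxO without DMSO 1 or enzalutamide 1, 2 or 4 (0.0469 to 0.0493). With the replicate number as a block 5296 genes changed (2659 higher, 2637 lower) and 13 lists and 3 fixed genes were called. Same-numbered libraries had correlations of -0.00849 to 0.0451, none of the 5 over 0.1, and 3 of 5 DMSO libraries correlated best with their own number. These low correlations show no strong pairing by number, but the 3 matches leave a weak pairing open. Of 130 named genes that passed, 122 kept call and direction throughout, and Rbp4, Isl1, Nr1i3, Abat, Ndufs7, mt-Nd2, E2f1 and Atp6v1h lost the call at least once. The named genes and lists that turned direction had not passed the test. Mafa had 0.15 under the block, 0.16 in limma-voom, 0.15 and 0.11 in limma-trend, and -0.32 to 0.36 with 1 library left out. With GC and length trends removed the log2 fold changes were -0.0481 for Nkx6-1, -0.0958 for Irx1, -0.0373 for Irx2, -0.0513 for Phlda1 and 0.0367 for Spry2 (0.0344 with total-count scaling). With 1 library left out they ran from -0.00276 to 0.0526 for Irx1, from -0.0112 to 0.0215 for Irx2, from -0.0175 to 0.0458 for Phlda1 and from -0.0378 to 0.0572 for Spry2. The δ, PP and ε cell and lipogenesis lists turned with relative log expression factors (0.996 each), no filter (0.952 each), the block (0.966 and 0.973), GC and length trends removed (0.792 each) and mitochondrial mRNAs and Gcg omitted (0.997 each), the former also with fry (0.988), and the secretory granule list with no filter (0.83). With 1 library left out the adjusted p ran from 0.877 to 0.994 for the δ, PP and ε list, from 0.877 to 0.998 for lipogenesis and from 0.585 to 0.994 for hypoxia. The causes were not tested. Neurog3, Pax4 and the hormone genes without counts could not be tested, and a count of 0 allows a level of up to 0.0437 to 0.0504 CPM at this depth.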

Other observations

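The 4 lists in this part were chosen after the main results were seen. The tests of ERK output, synthetases, the mitochondrial chaperone list and the clock list were fixed before their own results were seen. Exceptions were the use of fry on the clock list, the dropped reading of its camera result, and the spread applied to the mitochondrial chaperone count. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 13 of 20 genes higher and 3 lower (13 and 3 adjusted over the list alone), with a median log2 fold change of 0.23. Camera over the 4 added lists gave an adjusted p of 9.81e-10, and an adjusted p = 0.036 with an estimated correlation. The synthetase genes Lars, Aars, Nars and Eprs rose with log2 fold changes of 0.48, 0.47, 0.46 and 0.40. Among mitochondrial chaperones and proteases, Lonp1, the protease of the mitochondrial matrix, rose from 344 to 673 CPM (log2 fold change 0.97, SE 0.0299), and the chaperone gene Hspa9 rose from 797 to 1036 CPM (0.38, SE 0.0242). That list had 3 of 10 genes higher and 4 lower (3 and 4 adjusted over the list alone), and camera called it higher, with an adjusted p of 0.0272 (adjusted p = 0.176 with an estimated correlation).

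Dusp6, Etv5, Egr1 and Fos, all induced by ERK signalling, fell, with log2 fold changes of -2.37, -1.98, -1.23 and -2.44. These genes were grouped after their values were seen. Egr1 and Fos belong to the cAMP and immediate early list, where 8 of 14 members fell, 2 rose and 4 did not pass. Those 4 were Jun (-0.07), Junb (0.03), Ier2 (-0.02) and Dusp1 (-0.05), with adjusted p-values of 0.278 to 0.962 in edgeR's test. A candidate explanation is lower ERK pathway transcription. The test used the 8 genes of a 10-gene ERK output list other than Dusp6 and Etv5, which had prompted it: of the 5 that were measured, 2 fell, 0 rose, and the median log2 fold change was -0.39. The genes that fell were Spry4 (-1.98), an inhibitor of the pathway, and Dusp4 (-0.57), a phosphatase of ERK. The others did not pass, namely Ccnd1 (-0.39, adjusted p = 0.102, and 0.0238 without DMSO library 4), Phlda1 (0.00801) and Spry2 (-0.000489). Of all 14156 genes tested 37.9% changed and 2662 fell, so 2 falls among 5 genes are not in themselves unusual. The whole list had 4 of 7 measured genes lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 6.37e-06; adjusted p = 0.00544 with an estimated correlation), which is not independent of the genes that led to it. The direction was as the hypothesis predicts, on few genes, and ERK activity itself was not measured.

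Per1 and Bhlhe40, which take part in the circadian clock, rose with log2 fold changes of 0.50 and 0.30. Whether the circadian clock genes shifted as a group cannot be told apart from separate changes of single genes. Camera over the 4 added lists gave an adjusted p of 0.53, but it tests for a common direction, and a clock shift can move its arms in opposite directions. Its planned reading as evidence against a shift was therefore dropped after the result was seen. The mixed test of fry, which allows both directions but does not compare the list with other genes, gave an adjusted p of 3.93e-09. As 37.9% of all genes tested changed, such a test can pass for many lists. Its adjusted p for lipogenesis, which camera did not call, was 4.13e-11. Of 11 measured clock genes 3 were higher and 2 lower (4 and 2 adjusted over the list alone). Cry2 (0.53), Cry1 (0.25) and Dbp (0.30, and 0.20 with GC and length trends removed) rose, and Per2 (-0.44) and Arntl (-0.26) fell.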
